A study of Homo sapiens with 53 samples.

How the data were processed

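RNA was measured at day 2 of a cardiac differentiation of human embryonic stem cells, the stage that the labels call mesoderm. The cells were the H9 line carrying an MLC2v:H2B reporter. The labels describe stepwise modulation of WNT signalling as the means of differentiation, and CRISPR/Cas9 targeting of exon 1 of ZIC3 as the origin of the knockout lines. There were 3 wild-type and 3 ZIC3 knockout RNA libraries. The series lists 53 samples, and the other 47, which are 12 ATAC-seq and 35 ChIP-seq samples, were not analysed here.

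The deposited table gives FPKM values, made by the authors, for 60492 rows, each a transcript of 1 annotated gene with its exonic length. Total RNA was extracted with Trizol and made into libraries with an Illumina TruSeq kit, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.17, Bowtie2, STAR, HOMER and the build hg19 were used, with no role or order given. Strandedness and the rule that chose a transcript per gene are not given in the sources used here. Reads of genes that overlap, of antisense partners and of near-identical copies could therefore be assigned to either gene.

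The FPKM values keep the depth. Multiplied by length, they were whole multiples of 1 step per library, which is the value of 1 read, in 100% of the 16736 to 20167 low values checked per library, with a tolerance of 0.1 read. The rows held about 42600000 to 59100000 reads per library, or 53.1% to 56.9% of the read total that the values were scaled by. The median tested gene had 492 reads in its shallowest library, so counting error was small for most genes. The depth of each library is given with the results.

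Before the data were examined, the comparison, the gene lists, the rule for named genes and the alternatives were fixed. For symbols with several rows, the row with the highest mean FPKM was kept, and genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 15375. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 30 lists with at least 3 tested members. Members were also adjusted over the list alone. Chromosomes with at least 20 tested genes were tested with camera in the same way.

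The replicate numbers in the labels were checked for pairing by a fixed rule, that each same-numbered pair correlates above 0.1. The deviations of same-numbered libraries from their group means correlated across genes at 0.77, 0.79 and 0.42 for replicates 1, 2 and 3, so the numbers were taken to pair the libraries. This pairing comes from the data and from the shared numbers, and the labels do not say what a number stands for. It is clearest for replicate 1. Wild type replicate 3 correlated more with knockout replicate 2, at 0.64, than with its own number. Because replicate 1 dominates the deviations, replicates 2 and 3 correlate largely through their shared contrast with it. The difference of replicate 2 minus replicate 3 correlated between the genotypes at 0.25, a direct check that leaves replicate 1 out. The fit with the replicate number as a block is given beside the results whose call it changes. The labels do not say that replicates are separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Camera p-values at the preset correlation compare the genes of a list or chromosome with all other genes. They treat genes as nearly independent and do not measure how a list varies between libraries.

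The named genes are ZIC genes, then the 12 highest and 12 lowest log2 changes among genes past the threshold whose groups do not overlap. Symbols that start with LOC, LINC, MIR or SNOR, or that hold a hyphen followed by AS, were left out of these. From each list come up to 4 members with the smallest p among those past the threshold, or up to 2 members where none passed. Since no gene passed without the block, the parts of the rule that need a threshold were applied to the blocked fit, and a list member counted as past the threshold if it passed over all genes or adjusted over the list alone. That reading was chosen after the unblocked result was seen. The fixed list for HOX genes was not tested because all 39 genes were below the filter.

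On simulated data for this comparison, with 15375 genes of which 200 were changed, drawn 5 times, the blocked fit recovered 77.0% of genes changed by a log2 of 1 and 100% of those changed by 2 or 3. It also called 15 unchanged genes on average. The fit without the block recovered 0.299%, 46.0% and 80.0%, and called 0 unchanged genes. The simulation gave both genotypes the same replicate means and took its noise from the blocked fit, so exact pairing was built in. The gap between the 2 fits was therefore set by the design of the simulation. It does not show that the block suits the measured libraries.

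The alternatives were other pseudocounts, filters, scalings, row choices, variance models and thresholds, the replicate block, leaving out each library, and for lists an estimated correlation and fry. The planned count-based test was not applicable to FPKM. Chosen after seeing the data were limma's voom on the recovered reads, the blocked fit under each other setting, a block of replicate 1 against the other replicates, and leaving out a replicate number in both genotypes. Coordinates are those of the deposited table, on hg19, counted from 1. Figures were drawn with matplotlib 3.10.9.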

Results

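RNA levels were compared between 3 wild-type and 3 ZIC3 knockout libraries of day 2 mesoderm, made from the H9 human embryonic stem cell line with an MLC2v:H2B reporter. ZIC3 is a zinc-finger transcription factor whose mutation is known to disturb left-right patterning and heart formation. The comparison asks which genes differ when ZIC3 is lost at the mesoderm stage. The wild-type libraries held about 57500000, 51600000 and 57100000 reads in the table, and the knockout libraries held about 59100000, 44900000 and 42600000.

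Replicate 1 of both genotypes stood apart from the other libraries. The first principal component took 71.4% of the variance and placed replicate 1 at −86.3 in wild type and −52.8 in the knockout, against 20.4 to 45.01 for the other 4 libraries. The second component took 15.5%. The mitochondrial share of reads was 0.367% in wild type replicate 1 and 1.68% in knockout replicate 1, against 3.18% to 4.49% in the others. The medians within each numbered pair are therefore given below for the lists that passed.

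**Figure D1:**
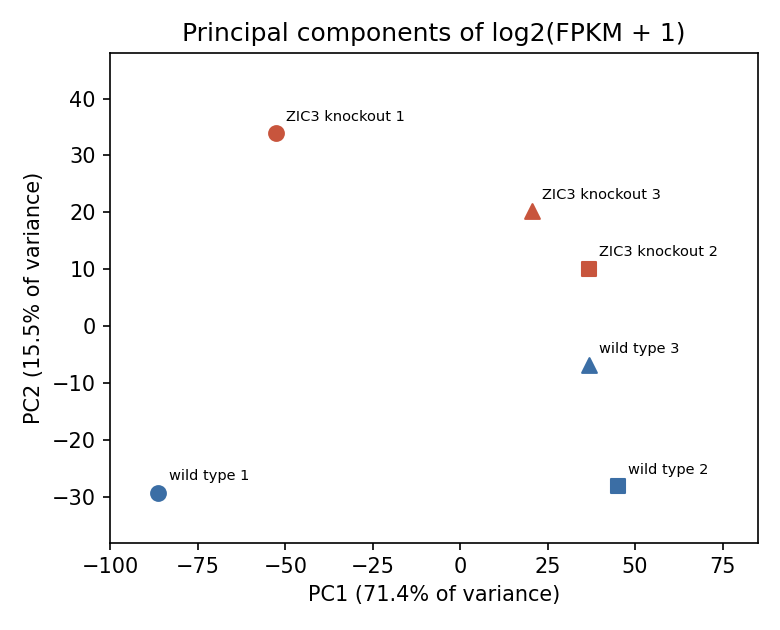
Principal components of log2(FPKM + 1) over 15375 genes, 1 point per library, coloured by genotype and shaped by replicate number. The replicate 1 libraries lie at −86.3 and −52.8 on the first axis, and the other 4 lie between 20.4 and 45.01.

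ZIC3 RNA was lower in the knockout in all 3 pairs. ZIC3 (ENSG00000156925, chromosome X, 136648677 to 136659850, plus strand) was at 364, 268 and 190 FPKM in wild type and 40.2, 31.2 and 41.9 FPKM in the knockout. The means were 274 ± 87.5 and 37.8 ± 5.74 FPKM (SD, n = 3 each), a 7.26-fold difference and a log2 change of −2.79 (SE 0.23 with the replicate block). The limma adjusted p was 0.0931 without the block and 0.0314 with it. An exact permutation test of 3 against 3 libraries gave p = 0.1, the smallest that the 10 splits allow. The row shares bases with RP11-158M9.1, so its reads may include some of that gene. Of its relatives, ZIC2 averaged 112 ± 46.0 FPKM in wild type and 154 ± 46.0 in the knockout (log2 change 0.49), and ZIC5 averaged 3.73 ± 1.12 and 6.06 ± 0.617 FPKM (log2 change 0.60). The ZIC2 libraries overlapped between the genotypes. With the block, both passed adjusted over the list alone, which neither did without it. That list has 3 tested genes, ZIC3 itself among them, so the adjustment is slight. The unadjusted blocked limma p was 0.0191 for ZIC2 and 0.0305 for ZIC5, and 1716 of 15375 genes lay under 0.05 with the block. Neither gene passed over all genes, with blocked limma adjusted p of 0.308 and 0.373. The ZIC2 change was 0.24 without wild type replicate 3, 0.25 without knockout replicate 1 and 0.79 without wild type replicate 1. ZIC1 and ZIC4 were below the filter at mean levels of 0.113 and 0.0200 FPKM. As a list, the 3 tested ZIC genes had a median log2 change of 0.49 and a mean of −0.57, and camera, which gave the negative direction, did not pass (adjusted p = 0.625).

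**Figure D2:**
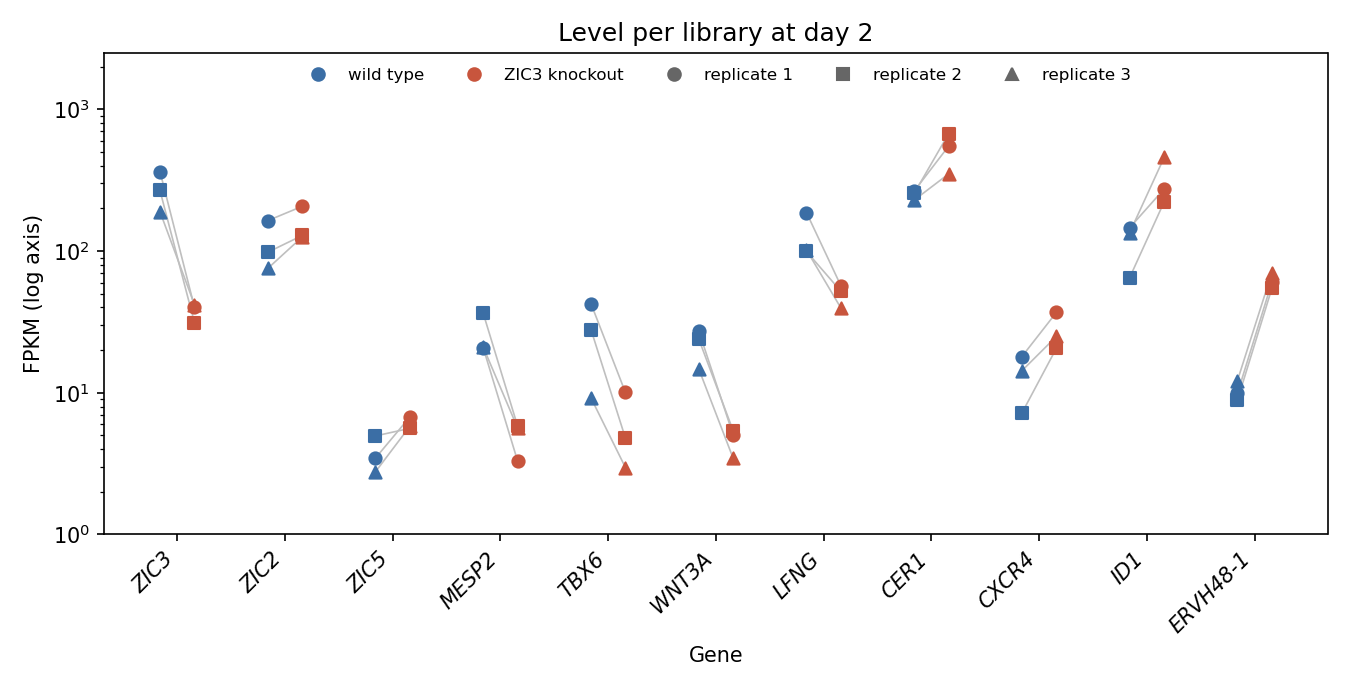
FPKM on a log axis for 11 named genes in each library, with wild type at the left and ZIC3 knockout at the right of each gene, symbols for replicate numbers and lines between libraries of the same number. ZIC3 was at 190 to 364 FPKM in wild type and at 31.2 to 41.9 FPKM in the knockout.

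With the replicate block, 50 of 15375 genes passed, 23 higher and 27 lower in the knockout, and 44 of them were protein-coding. That count moved with the setting. It was 1058 without replicate 1 and 643 without replicate 3 of both genotypes, 107 with quantile normalization, 32 with robust eBayes, 28 and 18 with pseudocounts of 0.5 and 0.1, 16 with median-of-ratios scaling, 1 at a mean of at least 5 FPKM and 0 with no filter on low values. Without the block, limma called 0 genes, with a smallest adjusted p of 0.0862 and 648 genes at an unadjusted p under 0.05, against 769 expected by chance. The blocked count at an unadjusted p under 0.05 was 1716, where the same 769 would be expected. Of the 50 genes, 43 had no overlap between the genotypes. Over all tested genes 1552 had none, which is 10.1%, where chance gives 10% if all libraries are exchangeable. Both this 10% and the unblocked 769 assume no difference shared by libraries of the same number. The difference of replicate 1 breaks that, so they are not a chance level for paired libraries. Genes named from lists did not need to be free of overlap. Of those past the threshold over all genes or over the list alone, TBX6, DLL3, FGF4, CRABP1, LMO2, ZIC2, FOXA3 and RUNX1 overlapped. HNF4A, MEG3, EGLN3, ENO2, CLDN7, TBX3, GRHL3 and RAB25 did so too.

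Among genes past the threshold over all genes, those that fell most included PPP1R1B, a regulator of protein phosphatase 1, and CD177, a surface glycoprotein. PPP1R1B (chromosome 17, 37784751 to 37792878) went from 36.8 ± 12.4 to 2.42 ± 2.36 FPKM, and CD177 (chromosome 19, 43857843 to 43858677) from 12.9 ± 6.30 to 0.416 ± 0.116 FPKM (SD, n = 3 each). Their log2 changes were −3.64 and −3.19, with blocked limma adjusted p of 0.0236 and 0.0361. TESC fell by 2.54, GNG8 by 2.35, LRRC55 by 2.26, PNMT by 2.12, KCNK17 by 2.08, TNFRSF11B by 2.07 and NKAIN4 by 1.87 on the log2 scale. The transcription factor MESP2 and the ligand WNT3A, described with their lists, were among the 12 lowest. Among genes past the threshold over all genes, those that rose most were CALHM2, ERVH48-1 and ISM1. ERVH48-1, a locus derived from an endogenous retrovirus (chromosome 21, 44336913 to 44345756), went from 10.3 ± 1.70 to 61.8 ± 8.02 FPKM (log2 change 2.47, blocked limma adjusted p = 0.0236). CALHM2, a calcium homeostasis modulator (chromosome 10, 105206546 to 105212075), went from 0.187 ± 0.0398 to 6.29 ± 1.32 FPKM (log2 change 2.60), and its row shares bases with RP11-225H22.7. MAGEH1 on the X chromosome (55478538 to 55479999) was at 0.0950, 0 and 0.0260 FPKM in wild type and at 3.94, 2.94 and 3.45 FPKM in the knockout. The secreted protein ISM1 rose by a log2 of 2.26, CCDC3 by 2.19, PCAT14 by 2.08, SLC52A3 by 1.95, the hormone STC1 by 1.74, ADAMTS18 by 1.58, CRHBP by 1.56 and ACP5 by 1.56. AC007326.11 rose by 1.74 and shares bases with AC007326.13.

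Genes of the presomitic and paraxial mesoderm, which forms the somites, were lower in the knockout. Of 10 tested members, 8 fell and 0 rose adjusted over the list alone with the block, 1 of them also over all genes, and without the block 5 fell. TBX6, a transcription factor of paraxial mesoderm (chromosome 16, 30097356 to 30102534), went from 26.6 ± 16.8 to 5.94 ± 3.68 FPKM (log2 change −1.89, blocked limma adjusted p = 0.0494 over all genes), though its genotypes overlapped. LFNG, a modifier of Notch receptors, went from 130 ± 49.9 to 49.5 ± 8.89 FPKM, FOXC2 from 2.78 ± 1.07 to 0.443 ± 0.185 FPKM and FOXC1 from 7.02 ± 2.99 to 2.55 ± 1.22 FPKM. LFNG shares bases with MIR4648. The median log2 change was −1.21, and it was −1.52, −1.01 and −0.73 in pairs 1, 2 and 3. Camera gave an adjusted p of 6.2e-10, and the adjusted p was 0.373 with an estimated correlation.

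Of 22 tested primitive streak and nascent mesoderm genes, 6 fell and 0 rose adjusted over the list alone with the block, and 2 fell over all genes, while 3 fell without the block. TBX6, also a member of the presomitic list, was among the 2 that fell over all genes. MESP2 (chromosome 15, 90303832 to 90321905) went from 26.1 ± 8.95 to 4.90 ± 1.40 FPKM, with a blocked limma adjusted p of 0.0361. The apelin receptor gene APLNR went from 403 ± 205 to 117 ± 28.8 FPKM, and SNAI2, a repressor of epithelial genes, from 9.98 ± 7.68 to 2.17 ± 1.09 FPKM. The list had a median log2 change of −0.36 and a camera adjusted p of 1.2e-04, and the adjusted p was 0.373 with an estimated correlation. The medians were −0.66 and −0.35 in pairs 1 and 2 and 0.12 in pair 3. Without replicate 1 of both genotypes the adjusted p was 0.0676, and without wild type replicate 1 alone it was 0.0718.

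WNT signalling genes were lower as a group. Of 26 tested members, 7 fell and 1 rose adjusted over the list alone with the block, 2 fell over all genes, and without the block 3 fell. WNT3A (chromosome 1, 228194752 to 228248961) went from 22.1 ± 6.55 to 4.63 ± 1.04 FPKM (log2 change −2.01, blocked limma adjusted p = 0.0314). MYC went from 40.8 ± 16.1 to 12.5 ± 3.11 FPKM, the WNT target AXIN2 from 25.0 ± 4.77 to 13.0 ± 1.28 FPKM and the receptor gene FZD7 from 112 ± 42.8 to 60.6 ± 11.97 FPKM. The median log2 change was −0.43, with camera adjusted p of 5.0e-05 and an adjusted p of 0.373 with an estimated correlation. The medians were −0.55, −0.41 and −0.18 in pairs 1, 2 and 3. The FZD7 log2 change of −0.83 was −0.53 without wild type replicate 1.

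Of 12 tested hedgehog genes, the receptor gene PTCH1 (29.1 ± 10.6 to 12.7 ± 0.362 FPKM) and the co-receptor gene BOC (5.92 ± 1.51 to 3.00 ± 1.57 FPKM) fell adjusted over the list alone with the block, so 2 fell and 0 rose. Neither passed without the block, where 0 fell. The camera adjusted p was 0.00698, or 0.373 with an estimated correlation, and 0.194 without wild type replicate 1. The medians were −0.22, −0.25 and −0.30 in pairs 1, 2 and 3, and the BOC log2 change of −0.85 was −0.56 without knockout replicate 3. Of 12 Notch genes 3 fell and 0 rose in the same way, and 1 fell without the block. The 3 were DLL1, DLL3 and LFNG, which are all members of the presomitic list too, so this result is not separate from that one. DLL1, a Notch ligand, went from 15.9 ± 8.87 to 3.26 ± 2.78 FPKM and DLL3 from 155 ± 80.5 to 67.6 ± 42.4 FPKM. The camera adjusted p was 0.0347, or 0.434 with an estimated correlation, and it was 0.474 without replicate 1 of both genotypes, 0.498 without wild type replicate 1 and 0.0600 without knockout replicate 1. The median was −0.61 in pair 1, 0.0026 in pair 2 and −0.02 in pair 3. The DLL3 log2 change of −1.26 was −0.76 without knockout replicate 1. Of 12 retinoic acid genes, CRABP1, a retinoic acid binding protein, was the 1 that fell (275 ± 155 to 132 ± 78.2 FPKM), and 0 fell without the block. Camera gave an adjusted p of 0.0478, or 0.373 with an estimated correlation. That call was lost without replicate 1 of both genotypes (0.0676), without wild type replicate 1 (0.5005), and without knockout replicate 2 (0.0659) or 3 (0.114). The medians were −0.17, −0.27 and −0.28 in pairs 1, 2 and 3, and the CRABP1 log2 change of −1.04 was −0.62 without wild type replicate 1. Of 24 FGF and ERK response genes, 1 rose (PHLDA1, log2 change 0.99) and 1 fell (FGF4, log2 change −1.14), neither of them without the block, and the list did not pass (adjusted p = 0.857).

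The definitive endoderm list passed camera as higher in the knockout, though most of its members did not pass on their own. Of 15 tested members, 12 had a positive and 3 a negative log2 change, and 5 rose and 0 fell adjusted over the list alone with the block, and none of these passed over all genes. Adjusted over the list alone without the block, 0 passed. The secreted antagonist CER1 went from 250 ± 18.9 to 525 ± 164 FPKM and the chemokine receptor CXCR4 from 13.2 ± 5.50 to 27.5 ± 8.44 FPKM. FOXA3 went from 24.4 ± 9.32 to 39.0 ± 7.62 FPKM and HNF4A from 0.566 ± 0.590 to 2.00 ± 0.913 FPKM, and both overlapped between the genotypes. The median log2 change was 0.70, and it was 0.09, 0.98 and 0.61 in pairs 1, 2 and 3. Camera gave an adjusted p of 5.4e-05, or 0.517 with an estimated correlation, and 0.0692 without wild type replicate 2. Without that library the log2 change of CXCR4 was 0.70 in place of 1.05, and that of FOXA3 was 0.44 in place of 0.70. Of 19 nodal and left-right genes 4 rose and 1 fell adjusted over the list alone with the block, and 0 did so without it. LEFTY2, a nodal antagonist, went from 45.3 ± 10.9 to 10.5 ± 8.87 FPKM and shares bases with RP4-559A3.6. PITX2, a left-right transcription factor, went from 3.67 ± 0.289 to 7.09 ± 2.09 FPKM and GDF3 from 0.410 ± 0.152 to 1.60 ± 0.803 FPKM. The GDF3 log2 change of 0.85 was 0.53 without replicate 1 of both genotypes. The list did not pass (adjusted p = 0.333).

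BMP signalling genes moved in both directions, with more of them higher. Of 20 tested members, 8 rose and 4 fell adjusted over the list alone with the block, and 6 rose and 0 fell without it. The BMP targets ID1 and ID2 went from 115 ± 44.0 to 318 ± 124 FPKM and from 73.8 ± 19.4 to 150 ± 36.9 FPKM, and BAMBI from 22.1 ± 5.91 to 50.02 ± 19.8 FPKM. MSX2 went from 8.93 ± 3.12 to 31.6 ± 20.1 FPKM and was at 54.7 FPKM in knockout replicate 3, against 17.8 and 22.3 in the other knockout libraries. The median log2 change was 0.45 and the camera adjusted p was 3.1e-04, or 0.482 with an estimated correlation, and 0.0662 without wild type replicate 1. The medians were 0.51, 0.21 and 0.81 in pairs 1, 2 and 3.

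**Figure D3:**
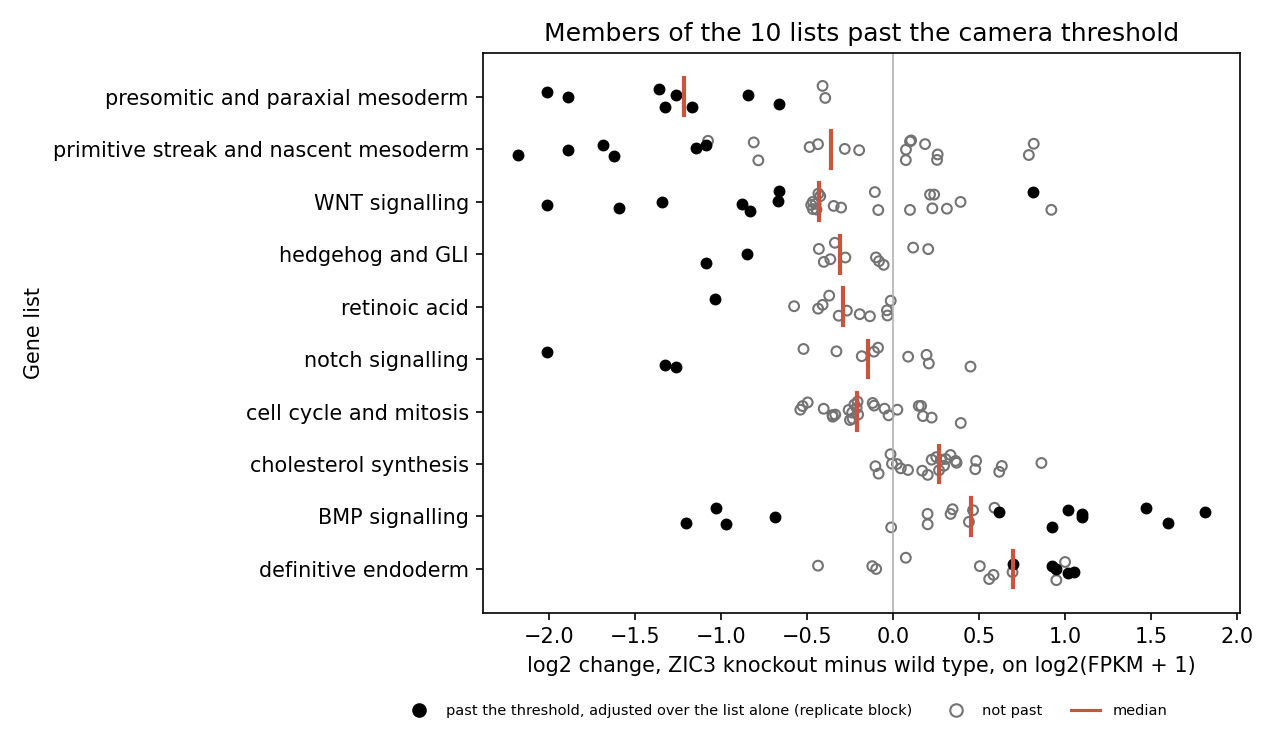
The log2 change of each tested member of the 10 lists past the camera threshold, knockout minus wild type, with filled points for members past the threshold adjusted over the list alone with the replicate block, open points for the rest and a red line at the median. The median is −1.21 for presomitic and paraxial mesoderm and 0.70 for definitive endoderm.

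Lists of other cell types held single genes that changed without a call for the list. Adjusted over the list alone without the block, 1 gene fell in the cardiac mesoderm list, 1 rose and 1 fell in the surface ectoderm list, and 0 passed in the lateral plate, neural crest and endothelial lists. In the cardiac mesoderm list (adjusted p = 0.538) 2 of 14 members rose adjusted over the list alone with the block, ISL1 (log2 change 1.48) and FGF10 (0.65), and 2 fell, FOXC1 and FOXC2. Its median was 0.08 and its mean and test were negative. ISL1 was at 10.96 FPKM in knockout replicate 3, against 2.13 and 3.39 FPKM in the others, and its log2 change was 0.91 without that library. In the lateral plate list (adjusted p = 0.349) 3 of 10 rose and 2 fell. GATA3 was at 13.9, 9.35 and 37.3 FPKM in the knockout, against 3.64 to 4.50 FPKM in wild type, TBX3 rose by a log2 of 1.47, and LMO2 fell by 0.83. The LMO2 change was −0.28 without wild type replicate 2 and −1.39 without knockout replicate 2. In the surface ectoderm and amnion list (adjusted p = 0.333) 3 of 9 rose, among them GRHL3 with a log2 change of 1.54 (0.89 without knockout replicate 3), and 1 fell, DLX3, with −1.01. In the neural crest list (adjusted p = 0.0891) 2 of 11 rose and 5 fell, among them SOX9 (−0.85), while ETS1 rose by 0.81. In the endothelial list (adjusted p = 0.850) RUNX1 rose by 0.76 (0.39 without wild type replicate 1) and LMO2 fell. No member of the cardiac muscle list (11 tested, adjusted p = 0.940) or the neural ectoderm list (8 tested, adjusted p = 0.538) passed. The neural ectoderm list passed without knockout replicate 1 (0.0164). The log2 changes of NPPA and NEBL were −0.79 and 0.38, and NPPA shares bases with NPPA-AS1. Those of OTX1 and DLK1 were −0.69 and 1.26, and that of OTX1 was −0.18 without wild type replicate 1. The cardiac muscle median was 0.04, its mean −0.04 and its camera direction positive.

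Genes of the epithelial to mesenchymal transition moved both ways. Of 20 tested, 9 rose and 5 fell adjusted over the list alone with the block, and 2 rose over all genes. The list did not pass camera (adjusted p = 0.939), which tests a shift in 1 direction and not changes both ways. Without the block 0 rose and 0 fell. Fibronectin (FN1) went from 188 ± 76.1 to 451 ± 170 FPKM and the epithelial genes RAB25 and CLDN7 from 11.03 ± 7.25 to 36.7 ± 24.9 FPKM and from 33.9 ± 20.3 to 82.8 ± 24.8 FPKM. The RAB25 log2 change of 1.64 was 1.08 without wild type replicate 2. CLDN7 shares bases with RP1-4G17.5. FN1 was the 1 gene of 23 extracellular matrix genes that passed with the block, with 0 without it, and that list did not (adjusted p = 0.939).

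Pluripotency genes did not pass as a list (14 tested, median log2 change 0.24, camera adjusted p = 0.0700), and no member passed. The list passed without knockout replicate 2 (0.00824) and without knockout replicate 3 (0.0205), and its adjusted p was 0.786 without replicate 1 of both genotypes. Their median was 0.60 in pair 1, −0.04 in pair 2 and 0.15 in pair 3. The log2 changes of L1TD1 and PRDM14 were 0.95 and 0.56. Cell cycle genes were lower as a list (25 tested, median −0.21, camera adjusted p = 0.00334, and adjusted p = 0.655 with an estimated correlation), with medians of 0.24, −0.43 and −0.36 in pairs 1, 2 and 3. No member passed, and the log2 changes of CCNA2 and PCNA were −0.54 and −0.52. That call was lost without wild type replicate 2 (0.254) or 3 (0.176). Cholesterol synthesis genes were higher as a list (23 tested, median 0.27, camera adjusted p = 0.00101, and adjusted p = 0.373 with an estimated correlation). The medians were 0.22, 0.04 and 0.43 in pairs 1, 2 and 3. No member passed, and the log2 changes of PCSK9 and MSMO1 were 0.86 and 0.63.

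The remaining lists did not pass with all 6 libraries. Adjusted p was 0.939 for p53 targets, 0.0700 for the unfolded protein response, 0.635 for heat shock and early response, 0.123 for glycolysis and hypoxia, 0.349 for ribosomal proteins, 0.0635 for imprinted genes and 0.374 for chromosome 20q11 genes. Leaving out libraries ended in a call for 6 of these. The unfolded protein response passed without knockout replicate 1 (0.0166) and without replicate 1 of both genotypes (0.0211). Imprinted genes passed without wild type replicate 1 (0.0279), without knockout replicate 2 (0.0145) and without replicate 1 of both genotypes (0.0178). Glycolysis passed without knockout replicate 2 (0.0145) or 3 (0.0111), and heat shock without knockout replicate 3 (0.0455). The p53 list passed without knockout replicate 1 (0.0169) and without replicate 1 of both genotypes (0.0178), in the other direction. Ribosomal proteins passed as higher without knockout replicate 3 (2.2e-04) and as lower without knockout replicate 1 (0.0111). The p53 median was −0.02 and its mean 0.02. Among members, ENO2 and EGLN3 of the glycolysis list rose by a log2 of 1.33 and 1.09 adjusted over the list alone with the block, and the ENO2 change was 0.76 without wild type replicate 2. The imprinted genes PEG10 and MEG3 rose by 2.34 and 1.01 in the same way, and PEG10 was at 198 FPKM in knockout replicate 3 against 55.0 and 48.9 FPKM in the others. ID1 passed among 20q11 genes with the block. In these 3 lists 0 members passed without it. The remaining named members did not pass, with log2 changes of 0.57 for PMAIP1, 0.55 for TP53INP1, 0.46 for PSAT1, 0.42 for XBP1, 0.47 for HSPA1A, −0.42 for FOS, 0.57 for RPS27 and −0.37 for RPS28. Ribosomal protein genes have near-identical pseudogene copies, and HSPA1A has a near-identical neighbour, so their values are uncertain.

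No chromosome passed as a set, with a smallest adjusted p of 0.0925 without the block and 0.153 with it. The median log2 change was 0.03 over all tested genes, 0.12 on chromosome X and 0.46 over 34 mitochondrial genes. Leaving out 1 library gave between 0 and 4 chromosomes. There were 4 without wild type replicate 2 and without wild type replicate 3, and 1 without replicate 1 of either genotype. The chromosomes called were 16 and 19, with lower values in the knockout, X with higher values, and the mitochondrial genes. The mitochondrial genes were lower without wild type replicate 1 and higher in the other 3 leave-outs that gave a call.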

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

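Chosen after seeing the data were the settings that combine the block with another choice, voom on the recovered reads, the block of replicate 1 against the others, and leaving out a replicate number in both genotypes. The unblocked count was 0 with limma under each planned setting except the replicate block, which gave 50 genes, and with voom, where the count was also 0. Leaving out libraries gave 0 to 41 genes, 41 being without replicate 1 of both genotypes. The blocked count of 50 became 18 and 28 with pseudocounts of 0.1 and 0.5, 0 with no filter on low values, 1 at a mean of at least 5 FPKM, 16 with median-of-ratios scaling, 107 with quantile normalization, 32 with robust eBayes, 0 at adjusted p under 0.01 and 130 with quantile-normalized voom. At a mean of at least 5 FPKM, 34 of the 50 genes were still tested and 1 of them was called, so fewer tested genes do not account for that fall. The causes of these moves were not tested. Leaving out a pair gave 38 to 1058 blocked calls, with 1058 without replicate 1, 38 without replicate 2 and 643 without replicate 3. All 50 genes were called again with quantile normalization and without replicate 1, 33 of 50 with voom and 16 of 50 with median-of-ratios scaling. The block of replicate 1 against the others gave 36 calls, among them 27 of the 50. Without replicate 2, 27 of the 50 were called again. Of the tested ones among the 50 genes, each kept its direction under those settings.

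The ZIC3 log2 change was −2.79 with the replicate block (adjusted p = 0.0314), −2.80 with blocked voom and −2.61 without replicate 1, and these 3 of 14 settings passed the threshold. It ranged from −3.03 to −2.56 when a library was left out, and adjusted p over all 14 settings ranged from 0.0138 to 0.675. For the other 87 named genes, 57 of 1188 checks passed the threshold where the unblocked fit did not, 45 of them with the block, and 4 checks on 3 genes changed sign. Over the leave-outs, FOS ranged from −1.15 to 0.21, NEBL from −0.0222 to 0.79 and RPS27 from −0.22 to 1.02. For 29 of the 87 genes the log2 change moved by over 1.5 times or turned when libraries were left out. Of these, 14 had passed with the block over all genes or adjusted over the list alone, and 15 had not. Among the 15, PCSK9 ranged from 0.33 to 1.32, TP53INP1 from 0.06 to 1.23, NPPA from −1.53 to −0.20, OTX1 from −0.996 to −0.18, CCNA2 from −0.78 to −0.33, PCNA from −0.69 to −0.32, XBP1 from 0.17 to 0.65, PSAT1 from 0.28 to 0.68, HSPA1A from 0.18 to 0.96, PRDM14 from 0.22 to 0.95, PMAIP1 from 0.30 to 0.87 and MSMO1 from 0.42 to 0.81.

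The number of gene lists past the threshold was 10 and became 0 with an estimated correlation and 0 with the replicate block and an estimated correlation. It was also 0 with fry and with blocked fry, each testing a shift in 1 direction. Camera with the block gave the same 10 lists. Leaving out libraries gave 6 to 13 lists, 6 being without wild type replicate 1. These 10 lists kept their direction under each of these settings. The estimated correlation was 0.018 for WNT, 0.027 for hedgehog and −0.0086 for retinoic acid, near the preset 0.01. A larger correlation alone therefore does not account for the loss of these calls. For the other lists past the threshold it ran from 0.093 for Notch to 0.673 for endoderm, with 0.358 for presomitic genes. The cause was not tested further. Retinoic acid was also lost with a pseudocount of 0.1 (adjusted p = 0.0562).

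Some lists that did not pass changed direction. The cardiac muscle list did so with the replicate block (adjusted p = 0.614), a pseudocount of 0.1 (0.974), median-of-ratios scaling (0.961), the block with an estimated correlation (0.828) and blocked fry (0.817). The p53 list did so with fry (0.994), the block (0.986), the block with an estimated correlation (0.996) and blocked fry (0.875). Over the leave-outs, adjusted p ranged from 0.0539 to 0.997 for cardiac mesoderm, 0.0827 to 0.997 for cardiac muscle, 0.0164 to 0.912 for neural ectoderm, 0.0732 to 0.997 for surface ectoderm, 0.252 to 0.951 for endothelial genes, 0.246 to 0.601 for FGF, 0.514 to 0.988 for epithelial-mesenchymal transition, 0.289 to 0.904 for extracellular matrix, 0.0169 to 0.925 for p53 targets, 0.0455 to 0.879 for heat shock, 0.0111 to 0.872 for glycolysis, 2.2e-04 to 0.667 for ribosomal proteins and 0.176 to 0.995 for chromosome 20q11. Without a change of direction, it ranged from 0.00824 to 0.786 for pluripotency, 0.0166 to 0.246 for the unfolded protein response and 0.0145 to 0.362 for imprinted genes. Chromosome calls ranged from 0 to 4 over the leave-outs and were 0 with the block and with an estimated correlation. Depth limits little here, since the median tested gene had 492 reads in its shallowest library.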

Other observations

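The tests of sequencing depth in each genotype, transcript length, a library batch, the role of replicate 1, delayed exit from pluripotency and chromosome parts, and those of other splits for the unblocked count and the chromosomes, were chosen after the results were seen. The 10 lists past the camera threshold were in the same direction in every setting that left out a library.

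Replicate 1 of both genotypes stood apart from the other libraries. In wild type, depth is argued against, since the recovered reads of replicates 1 and 3 differ by 1.01 times while these libraries lie at −86.3 and 36.8 on the first component. In the knockout, replicate 1 held 1.32 and 1.39 times the reads of replicates 2 and 3, so within the knockout depth and replicate 1 go together. The reads of wild type replicate 3 differ from those of knockout replicate 1 by 1.03 times, while the 2 lie 89.6 apart on the first component. The genotype gaps were 8.19 and 16.4 in replicates 2 and 3. That comparison crosses the genotypes, rests on 1 library of each and was the last of 3 tried. It therefore cannot exclude depth within the knockout. Thinning all libraries to the reads of the shallowest moved none by more than 0.0740 on that component, too little to test depth. A bias with the length of the deposited row is argued against by a Spearman correlation of −0.0659 across genes between that length and the replicate 1 difference (genes are not independent replicates). Each row holds 1 transcript, of 716 bases for FN1 and 378 for ZIC2, which need not be the one sequenced. A bias with the length of the RNA itself is therefore not excluded. A batch of RNA or libraries cannot be told apart from another shared condition of replicate 1. Subunits of 5 complexes whose genes had not been looked at (40 genes) had a scatter of 1.02 on the log2 scale between replicate 1 and the others, which lay at percentile 88.1 of 1000 draws of other genes matched on level (median 0.809), so it was not set apart from that of other genes. Relative to the scatter between replicates 2 and 3 this was 5.80 times, against a median of 3.12 times in the draws. For this ratio each scatter was first scaled for the number of libraries in its difference, so it is not their plain quotient. Of the draws, 1000 of 1000 lay at or below the 5.80 times. The subunits varied less than the draws between replicates 2 and 3 (0.203 against a median of 0.298), which raises that ratio. The scatter of the 2 genotypes correlated at 0.79, against a median of 0.71 in the draws. The statistic and its limits were chosen after the 5.80 times was seen, the upper limit after the percentile too. The first upper limit, the median of the draws, would have been passed, and the ratio in place of the scatter would have passed the later one. A first set of 4 complexes gave 8.16 times with the same scaling, but it held genes already seen to differ in replicate 1. GC content was not tested.

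The presomitic and WNT lists passed camera as lower and the endoderm list as higher in the knockout. The difference of replicate 1 was weighed as the whole cause for these 3 lists. All passed in the same direction without replicate 1 of both genotypes (3 of 3). Camera at the preset correlation also passed 3 to 12 lists in splits that mix the genotypes, so these passes cannot decide it. The list medians in pairs 2 and 3 were −1.01 and −0.73 for presomitic, −0.41 and −0.18 for WNT and 0.98 and 0.61 for endoderm genes. The shifts of the medians are thus not confined to pair 1. These 3 lists were chosen after the results were seen. Of the 10 lists past the camera threshold, 7 kept their call without replicate 1 of both genotypes. Primitive streak (camera adjusted p = 0.0676), retinoic acid (0.0676) and Notch (0.474) lost it. A delay in leaving pluripotency is a candidate explanation that cannot be told apart from an effect on lineage choice: the pluripotency list had a median log2 change of 0.241 and missed the threshold (adjusted p = 0.0700), with adjusted p from 0.00824 to 0.786 over the leave-outs and 0.786 without replicate 1 of both genotypes. A loss of ZIC3 itself, the difference that the labels name, stays among the open explanations, as untested. All these list calls were lost with an estimated correlation.

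The genes called with the block might come from a gained or lost chromosome part in the knockout line. This was checked over 8927 runs of 50 neighbouring genes, among 10054 genes with a mean of at least 5 FPKM. The largest median held in all 3 pairs was 0.122 in size, at chromosome 5, 140699661 to 149474611. That argues against a part as long as such a run, and shorter changes are not excluded. Some called genes lie close together and moved alike. PPP1R1B and PNMT on chromosome 17 fell, as did CD177 and CTC-490G23.2 on chromosome 19, while APOBEC3C and APOBEC3B-AS1 on chromosome 22 rose. Genes near 0 in wild type and present in the knockout, such as MAGEH1 and CALHM2, could also mark differences between clones rather than loss of ZIC3. The labels do not say how many clones the knockout libraries came from, so this was not tested.

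Other splits of the 6 libraries were too few to give a share under 0.05. The unblocked count was 0 genes in the real split and at most 0 in the others. With a real count of 0 each split gives as many by construction (10 of 10), so this says nothing. With the block, the real split gave 50 genes, and the highest of the other splits that part all 3 pairs gave 0, so 1 of 4 splits gave as many. For gene lists the real split gave 10, the other splits gave 3 to 12, and 3 of 10 splits gave as many. Each split that mixed the genotypes thus also passed some lists. A camera call at the preset correlation does not by itself mark a genotype difference. For chromosomes the real split gave 0 and the highest other 5, and 10 of 10 gave as many, again by construction.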
